A study of Mus musculus with 6 samples.

How the data were processed

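Total RNA was measured from myospheres, floating clusters grown from hind-leg muscle cells of male Balb/c mice that had been enriched with the surface antigen Sca1. Per the labels, the cells grew for 4 days in a neural stem cell medium supplemented with LIF, B27, EGF and an additive spelled bf6f, and RNA was prepared at passage 1 from 2000000 cells, in a volume of 5 µL marked as a small sample. There were 6 arrays: replicates 1 to 3, each hybridised to the Affymetrix chips MOE430A and MOE430B. The labels give all 6 arrays 1 submitter sample number and do not say whether the replicates are separate cultures. The series design text speaks of 1 sample and 6 replicates, so they may be repeat measurements of 1 RNA. The spread between these arrays may therefore be technical, and no p-value below is shown to extend to other cultures. P-values for gene lists come from a draw over genes, not from spread between samples. The replicate test measures replicates against disagreement between the chips on the same replicate. The main chip comparison uses the spread between arrays of the same chip.

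The deposited values are MAS5 signal intensity on a linear scale, per the submitters' processing notes, with no version given in the sources used here. In the deposited tables the mean signal after trimming 2% of probe sets from each end was 1500 to 1501 on every array, so the authors' scaling set each array, and each chip separately, to the same trimmed mean. MOE430A carried 22690 probe sets, of which 20393 had 1 gene symbol in the given annotation, 691 had several and 1606 had none. For MOE430B these numbers were 14674, 245 and 7656 of 22575. Symbols were updated through Entrez numbers in a RefSeq table of the mouse assembly GRCm38.p6, which held 20364 and 14499 of the single-gene probe sets, and probe sets with several genes or none were left out of gene results. Of the 276 listed genes, 17 had no single-gene probe set in that annotation and were not analysed here.

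Detection calls were not used here, so a background limit was set on each array from genes of tissues other than muscle: odorant, vomeronasal and taste receptors, keratin-associated proteins, defensins, gamma crystallins, sperm nuclear proteins, placental prolactins and testis kinases. The limit was the 95th percentile of their 149 probe sets on MOE430A and 44 on MOE430B. It came to 820.2, 785.4 and 822.1 on the MOE430A arrays of replicates 1, 2 and 3, and to 3237, 2929 and 2542 on the MOE430B arrays. A probe set counted as above the limit when it exceeded it on all 3 arrays of its chip, and a gene when at least 1 of its probe sets did. Of the reference probe sets themselves, 2.68% on MOE430A and 4.55% on MOE430B passed this rule. Having only 3 arrays per chip limits the precision here.

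For each of 18 gene lists the number of genes above the limit was tested against all measured genes with an exact hypergeometric test, two-sided, in strata of genes with 1, 2, or 3 or more probe sets, with Benjamini-Hochberg adjustment over the lists. The test takes genes as independent, which genes of a pathway are not. All measured genes include those on MOE430B only, where 10.3% of probe sets passed against 35.2% on MOE430A. The strata do not take the chip into account. Nearly all listed genes had a probe set on MOE430A, so their expected counts may run low. An alternative with MOE430A alone leaves out the genes on MOE430B only. Replicates were compared with limma 3.58.1 in R 4.3.3 (moderated F-test with an intensity trend, chip as covariate) on genes with a probe set above the mean limit on both chips, each gene being the mean log2 signal of those probe sets per chip. The chips were compared with limma on the 100 probe sets present on both, leaving out controls. Median shifts of lists between replicates were placed among 10000 random lists of the same size and matched mean signal. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

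The lists, tests and most alternatives were fixed before the data were examined. Genes named by rule are the first 4 of each list, all of the sex-linked list, the 10 genes with the smallest p between replicates, and the 5 shared probe sets with the largest chip difference in each direction. Other list members named below were chosen after their values were seen. A printed level is that of the gene's probe set with the highest mean signal, as mean ± SD over 3 arrays, and as the chips differ in scale, another probe set of the gene can lie nearer its own limit. Probe sets of shared sequence are those with IDs ending in _x_at, _s_at or _a_at, whose probes match several transcripts, in the last case transcripts of 1 gene. Signals on MOE430B run higher than on MOE430A for the same probe set, so each level is read only against the limit of its own chip. After the data were seen, 9 further lists and 4 alternatives were added: 2 other variance models for the replicate test, MOE430A alone, and each gene kept in its first list only. The last of these removed genes from the endothelial, immediate early and tendon lists alone and is counted as an alternative for these only, so the other lists had 11 alternatives.

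Tests were tried on simulated data. In the replicate comparison of 618 genes, limma recovered 12 of 30 genes changed by 1 on the log2 scale and 30 of 30 changed by 2, with 0 false calls. In the chip comparison of 100 probe sets it recovered 20 of 20 changed by 1, with 0 false calls. Both simulations gave all genes or probe sets the same spread on both chips, with independent normal noise. Spread that differs between genes or chips was not simulated. These counts therefore do not show how often the real data give false calls. Of 1000 random lists of 16 genes among 18024 genes, 3.1% had an unadjusted p under 0.05. The scanner records place all MOE430A arrays in 1 lot and the MOE430B arrays in 2 lots, replicate 1 apart from replicates 2 and 3, and give each chip its own scan day. These records were read without a script, and on MOE430A the recorded hybridisation day follows the recorded scan day, so the days are in doubt. If they are right, chip and day cannot be told apart.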

Results

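Gene expression was measured in cultured myospheres from Sca1-enriched mouse muscle cells, with 3 replicates on each of 2 chips and no second condition. The design therefore asks which genes gave a signal above background in these cells, whether the replicates differed, and how the chips compared. Of 18024 genes measured, 6567 (36.4%) were above the background limit in all 3 replicates. Genes with more probe sets passed more often: 22.4% of genes with 1 probe set, 42.5% with 2 and 59.1% with 3 or more. Across probe sets, log2 signals of replicate pairs correlated at 0.916 to 0.922 on MOE430A and 0.749 to 0.773 on MOE430B, correlations over probe sets that are not independent replicates. The mean limit was 809 on MOE430A and 2903 on MOE430B, and levels below are MAS5 signals on MOE430A unless MOE430B is named.

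Genes of the fibroblast extracellular matrix were above the limit for 23 of 23 measured against 9.56 expected (exact test, adjusted p = 1.52e-08). Col3a1, a fibrillar collagen, gave 61465 ± 3433 (SD, n = 3) and Col1a2, a chain of type I collagen, 62928 ± 4545. Decorin (Dcn), a small proteoglycan that binds collagen, reached 148494 ± 7522, and the gelatinase Mmp2 86203 ± 2106. Col1a1, above the limit by 1 of its 2 probe sets, varied more between arrays, at 5291 ± 2646, and Postn lay nearer the limit, at 1277 ± 365. This list passed under all 11 alternatives, with adjusted p no higher than 0.000143, though not always with every gene: 21 of 23 were above with the 99th percentile as limit, 20 of 21 without probe sets of shared sequence and 20 of 23 with 1 probe set per gene. Col1a1 lost its call in the last of these, at 0.0868 of the limit.

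Of surface markers listed for muscle stem cells, 8 of 8 measured were above the limit against 3.29 expected (exact test, adjusted p = 0.0075). No other cell type was measured for comparison, so the count does not show that these were muscle stem cells. Cd34, a sialomucin of progenitor cells, gave 10749 ± 740.4 and the transporter Abcg2 1728 ± 175 (SD, n = 3). The hyaluronan receptor Cd44 gave 6989 ± 759.6. Kit, the receptor of stem cell factor, was just above the limit at 977 ± 159.6, by 1 of its 2 probe sets, an _a_at set. The gene of the sort antigen itself, Ly6a, was not analysed here. The call was lost without probe sets of shared sequence (adjusted p = 0.0507), with 1 probe set per gene (0.0587) and with the array median as limit (0.0749).

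Markers of fibro-adipogenic and mesenchymal progenitors, the connective tissue cells of muscle, were above the limit for 10 of 16 genes against 6.22 expected, which did not pass (exact test, adjusted p = 0.154). Pdgfra, the receptor commonly used to define these cells, gave 12733 ± 791 (SD, n = 3). Pdgfrb gave 9363 ± 4871 by an _a_at probe set alone, Thy1 3639 ± 435 and Eng 1561 ± 165. The transcription factor Twist2 gave 15241 ± 1004, whereas Cd248, Osr1 and Dlk1 were not above the limit. With the 99th percentile as limit the list passed, at an adjusted p of 0.0289.

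**Figure D1:**
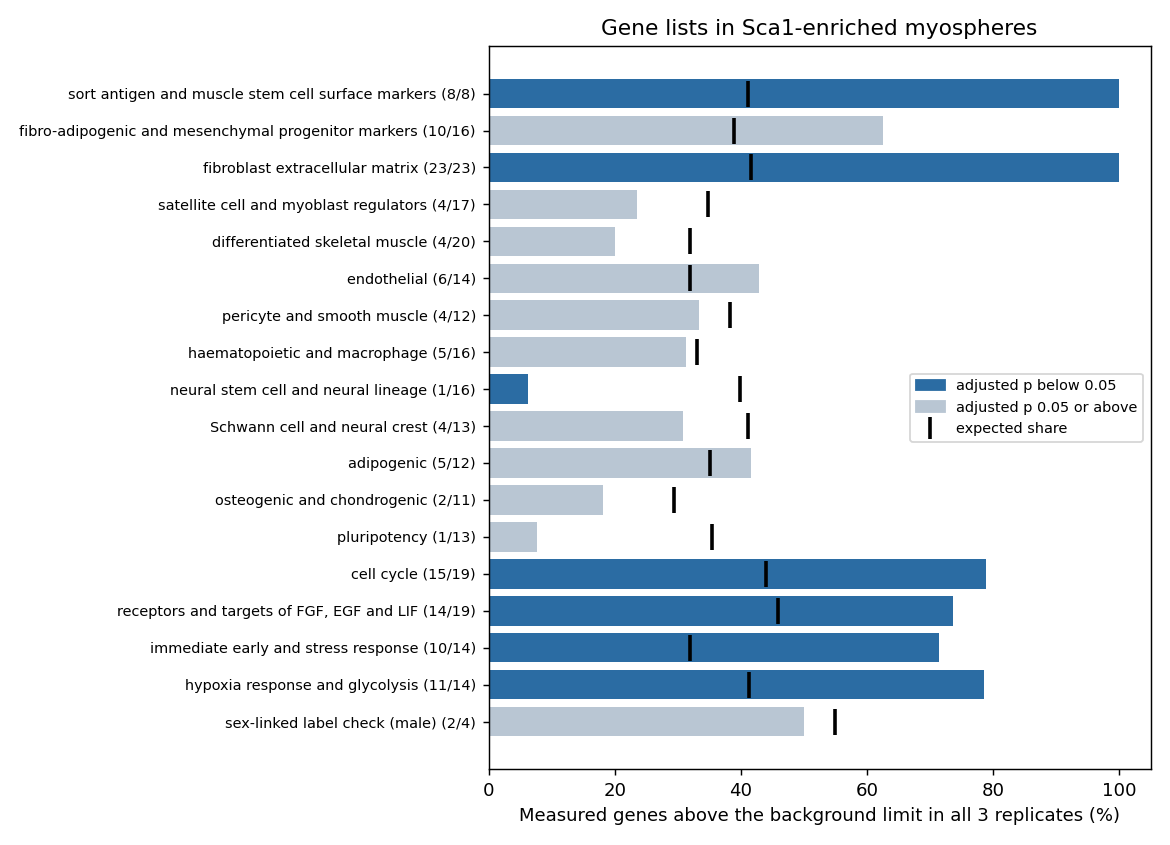
Bars show the percent of measured genes of each list above the background limit in all 3 replicates, with gene counts in brackets, and black marks the share expected from all genes. All measured matrix genes (23 of 23) were above the limit, and 1 of 16 neural genes was.

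Myogenic regulators were above the limit for 4 of 17 genes against 5.91 expected (exact test, adjusted p = 0.748). The satellite cell factor Pax7 gave 375.2 ± 238.7 on MOE430B, under that chip's limit, and Myf5 gave 76.8 ± 32.4 (SD, n = 3). The Pax7 probe set nearest its limit, on MOE430A, reached 0.37 of it on its lowest array. Myod1, which commits cells to the myoblast fate, gave 914 ± 267, and Myog, which acts in terminal differentiation, gave 1177 ± 393, each above the limit on 2 of 3 arrays. Members above the limit were Sdc4, Met, Chrna1 and Mef2c. Genes of differentiated muscle were above it for 4 of 20 against 6.38 expected (adjusted p = 0.62), namely Actc1, Ttn, Casq1 and Atp2a1. Acta1, skeletal actin, gave 819 ± 238, Myh3 447 ± 159.9 and Tnnt3 597 ± 365, and Ckm 1802 ± 134 on MOE430B, none of them above the limit on every array by any probe set. Neither list passed the test, and a gene under the limit is not shown to be absent.

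Among other cell types that a muscle digest can hold, no list passed the test. The test compares each list with the share over all genes, so it cannot exclude a minor cell type. Endothelial genes were above the limit for 6 of 14 against 4.47 expected (exact test, adjusted p = 0.784). These were Kdr, Esam, Egfl7, Robo4, Cldn5 and Eng. The receptor Kdr gave 1841 ± 326 (SD, n = 3), while Pecam1 gave 164 ± 81.3, Tek 469 ± 91.1 and Cdh5 908 ± 199.6. Pericyte and smooth muscle genes were above for 4 of 12 against 4.59 expected (adjusted p = 1), with Acta2 at 3410 ± 699.7 by a probe set of shared sequence alone, Rgs5 at 1602 ± 216, Tagln at 174 ± 113 and Myh11 at 103 ± 108. Abcc9 and Notch3 were the other pericyte and smooth muscle genes above it. Haematopoietic and macrophage genes were above for 5 of 16 against 5.28 expected (adjusted p = 1), namely Csf1r, Adgre1, Cd14, Lyz2 and Laptm5. The macrophage receptor Csf1r gave 2925 ± 555.0 and Cd14 4543 ± 578, whereas the leukocyte antigen Ptprc gave 628 ± 219.7, Cd68 792 ± 68.7 and Tyrobp 1018 ± 313, none of these 3 above the limit on every array.

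The culture medium was one for neural stem cells. Of neural genes 1 of 16 was above the limit against 6.39 expected, a lower share than in all genes (exact test, adjusted p = 0.015). That gene was Nes, an intermediate filament of neural and muscle progenitors, at 1875 ± 119.6 (SD, n = 3). The stem cell factor Sox2 gave 198 ± 54.1, the neuronal tubulin Tubb3 24.7 ± 12.6 and the astrocyte filament Gfap 680.4 ± 562 on MOE430B, while the Gfap probe set nearest its limit, on MOE430A, reached 0.665 of it on its lowest array. The call was lost with the 99th percentile limit (adjusted p = 0.104), without probe sets of shared sequence (0.0921) and with 1 probe set per gene (0.29). Schwann cell and neural crest genes were above for 4 of 13 against 5.35 expected (adjusted p = 0.825), with Sox10 at 1413 ± 429 by an _a_at probe set alone and S100b at 308 ± 42.0.

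Pluripotency genes were above the limit for 1 of 13 against 4.61 expected, which did not pass (exact test, adjusted p = 0.0951). Pou5f1 gave 67.4 ± 79.7, Nanog 33.7 ± 9.65, Zfp42 73.3 ± 29.8 and Dppa5a 523 ± 210.3 (SD, n = 3), and Fgf4 was the member above it. With receptor families alone as reference, 0 of 13 were above and the adjusted p was 0.0248. In that setting MOE430B had 15 reference probe sets, under the minimum of 20. Its limit was therefore that of MOE430A, moved by the median log2 difference of the shared probe sets. Adipogenic genes were above for 5 of 12 against 4.22 expected (adjusted p = 1). Lipoprotein lipase (Lpl) gave 83747 ± 3158, while the regulators Pparg and Cebpa gave 40.6 ± 23.3 and 471 ± 205. The fatty acid carrier Fabp4 gave 9552 ± 3085, by probe sets of shared sequence alone, the printed one an _a_at set. Osteogenic and chondrogenic genes were above for 2 of 11 against 3.23 expected (adjusted p = 0.825), Sp7 at 1077 ± 53.1 and Bmp2 at 1553 ± 553, while Sox9, at 702 ± 204, was above it on 2 of 3 arrays.

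**Figure D2:**
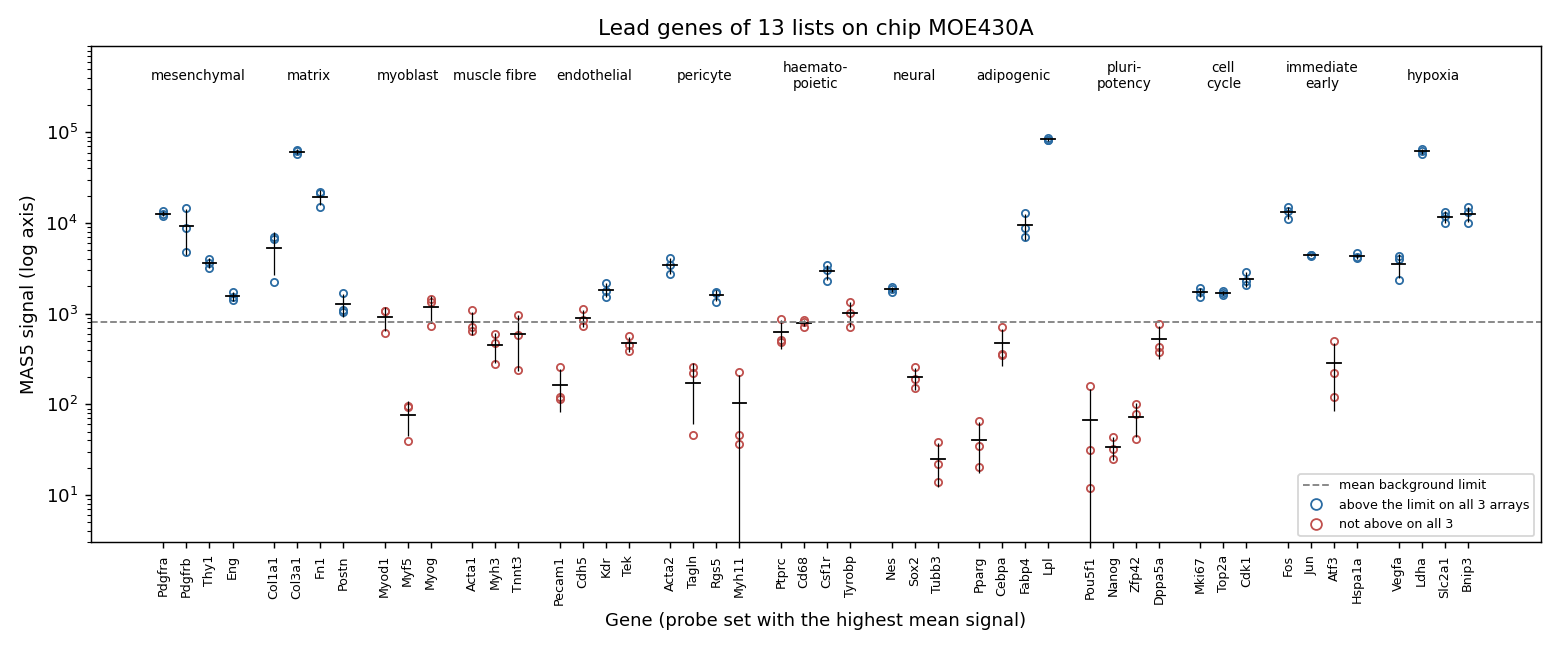
Circles give the MAS5 signal of each replicate on MOE430A (log axis) for the lead genes of 13 lists read on that chip, with bars for mean and SD (n = 3) and the mean limit dashed. Lpl at 83747 and Col3a1 at 61465 lie far above the limit of 809, and Tubb3 at 24.7 far below it.

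Cell cycle genes were above the limit for 15 of 19 against 8.36 expected (exact test, adjusted p = 0.014). The proliferation antigen Mki67 gave 1727 ± 186, topoisomerase Top2a, by an _a_at probe set alone, 1690 ± 81.2 and the mitotic kinase Cdk1 2428 ± 444 (SD, n = 3). Mcm3, Bub1, Tyms and Kif11 were not above it on all arrays. The call was lost under 6 of 11 alternatives, with adjusted p up to 0.497.

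Receptors and targets of FGF, EGF and LIF, the last 2 being supplements of the medium, were above the limit for 14 of 19 against 8.73 expected (exact test, adjusted p = 0.0495). The cytokine signalling inhibitor Socs3 gave 29205 ± 2996 (SD, n = 3) and Egfr 14963 ± 4516 on MOE430B. Lifr gave 173 ± 117 and was not above the limit, while its partner Il6st gave 11191 ± 714 on MOE430B. Fgfr1 was above it by 1 of its 3 probe sets alone, an _s_at set on MOE430A at 1148 ± 34.6. Its probe set with the highest mean, on MOE430B, read 1711 ± 646, under that chip's limit. This call was lost under 10 of 11 alternatives, with adjusted p up to 0.468, including each omission of a replicate.

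Immediate early and stress genes were above the limit for 10 of 14 against 4.47 expected (exact test, adjusted p = 0.015). The transcription factors Fos and Jun gave 13162 ± 2010 and 4410.1 ± 63.1, and the heat shock gene Hspa1a 4319 ± 279 (SD, n = 3). Atf3 gave 283 ± 198 and was not above the limit. With MOE430A alone 10 of 14 were above against 5.64 expected, and the adjusted p of the exact test was 0.0875.

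Genes of the hypoxia response and glycolysis were above the limit for 11 of 14 against 5.77 expected (exact test, adjusted p = 0.0197). Lactate dehydrogenase (Ldha) gave 62228 ± 3991, the glucose transporter Slc2a1 11768 ± 1672, Bnip3 12714 ± 2417 and Vegfa 3546 ± 1055 (SD, n = 3). Car9, Pdk1 and Ankrd37 were not above it on all arrays. The call was lost under 5 of 11 alternatives, with adjusted p up to 0.145.

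As a check of the male label, the Y-linked gene Eif2s3y was above the limit by 1 of its 2 probe sets, at 1530 ± 176 (SD, n = 3), while the other, on MOE430B, gave 432 ± 163, under that chip's limit. Kdm5d gave 507 ± 182 and Uty 598 ± 549 on MOE430B, neither above the limit by any probe set. Xist, which female cells transcribe from the inactive X, was above the limit only by the 1 of its 3 probe sets that is of shared sequence, at 1099 ± 40.3, and the other 2 gave 147 ± 116 and 116 ± 114, far below it. The list had 2 of 4 genes above against 2.20 expected (exact test, adjusted p = 1), a count that does not test the label, since a male label places Y-linked genes and Xist on opposite sides of the limit.

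Between arrays of the same titles, MOE430B gave higher signals than MOE430A for all 100 shared probe sets (limma, adjusted p under 0.05 for 100), by a median of 1.86 on the log2 scale. The largest differences, 2.59 to 2.35, were for Snrnp27, Tmem129, Mad2l1bp, Angel2 and Ddx24. Of these, the means of Tmem129 and Angel2 were under the mean limit on both chips and that of Mad2l1bp under it on MOE430A, so their sizes and order are uncertain, with an SE of 0.78 for Tmem129. Snrnp27, a splicing factor, read 1658 ± 652 on MOE430A and 9478 ± 1582 on MOE430B (SD, n = 3). No probe set was lower on MOE430B. Once each array was centred on the shared probe sets, 0 differed (limma; 10 at an unadjusted p under 0.05).

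Control probe sets for housekeeping transcripts were read at both ends of the transcript. The Gapdh control set at the 3' end read 87249 ± 5547 on MOE430A and the set at the 5' end 6497 ± 1347 (SD, n = 3). For actin these were 58522 ± 1853 and 5710 ± 968. The transferrin receptor sets read 325 ± 89.2 at the 3' end and 53.4 ± 39.0 at the 5' end, below the limit. The ratio of 3' over 5' signal averaged 13.8 on MOE430A and 15.4 on MOE430B for Gapdh, and 10.4 and 11.1 for actin. Sets at the middle of the transcript read 22426 ± 3254 for Gapdh and 10099 ± 1004 for actin on MOE430A. On MOE430B they read 83462 ± 17349 and 35237 ± 5177. Signal thus fell in order from the 3' to the 5' end for both genes on both chips, which goes with a loss of 5' signal. The transferrin receptor middle set, at 23.5 ± 10.7 on MOE430A, did not follow this order, but lay far below the limit. Probe sets differ in affinity, so the ratios alone do not measure RNA quality. A loss of 5' signal could leave probe sets far from the 3' end low. Genes may then be missed under the limit, which was not tested.

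Between replicates, 7 of 618 genes passed with limma (moderated F-test, adjusted p under 0.05; 64 at an unadjusted p under 0.05). They were Ep400, Thbs2, Zbtb20, Crtc3, Sesn3, Zdhhc6 and Cox8c, and replicate 2 was the lowest for 5 of the 7. Replicate 2 also had the highest hybridisation controls, in 9 of 9 probe sets on each chip, by a median of 1.67-fold on MOE430A and 1.45-fold on MOE430B over the other replicates. Ep400, a chromatin remodeller, was highest in replicate 3 and lowest in replicate 2, by 1.28 ± 0.25 (SE) on the log2 scale (limma, adjusted p = 3.21e-05). Thbs2, a matrix glycoprotein, was highest in replicate 2 and lowest in replicate 3, by 1.06 ± 0.21 (limma, adjusted p = 6.68e-05). Igfbp3, Ubxn11 and Zfp871 came next and failed, with limma adjusted p of 0.0576, 0.063 and 0.0711. The highest and lowest replicate kept their order on both chips for 5 of the 7, but not for Crtc3 and Cox8c, where Cox8c read 2.44 apart on MOE430B and -0.48 on MOE430A. With array median centring limma called 0 (31 unadjusted), although the 7 differences stayed about as large, at a median of 1.06 on the log2 scale before and 1.07 after, with a median SE of 0.267 before and 0.343 after. Limma called 0 with quantile normalization (36 unadjusted) and 0 without replicate 2 (39 unadjusted), and an ordinary F-test per gene called 0 (25 unadjusted). Of the 10 genes of all fixed lists in the test, 0 passed when adjusted over these 10 and 0 over all genes. Taking each list by itself, 1 gene passed adjusted over the list alone: Sparc, the only gene of the matrix list in the test, for which such an adjustment changes nothing.

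**Figure D3:**
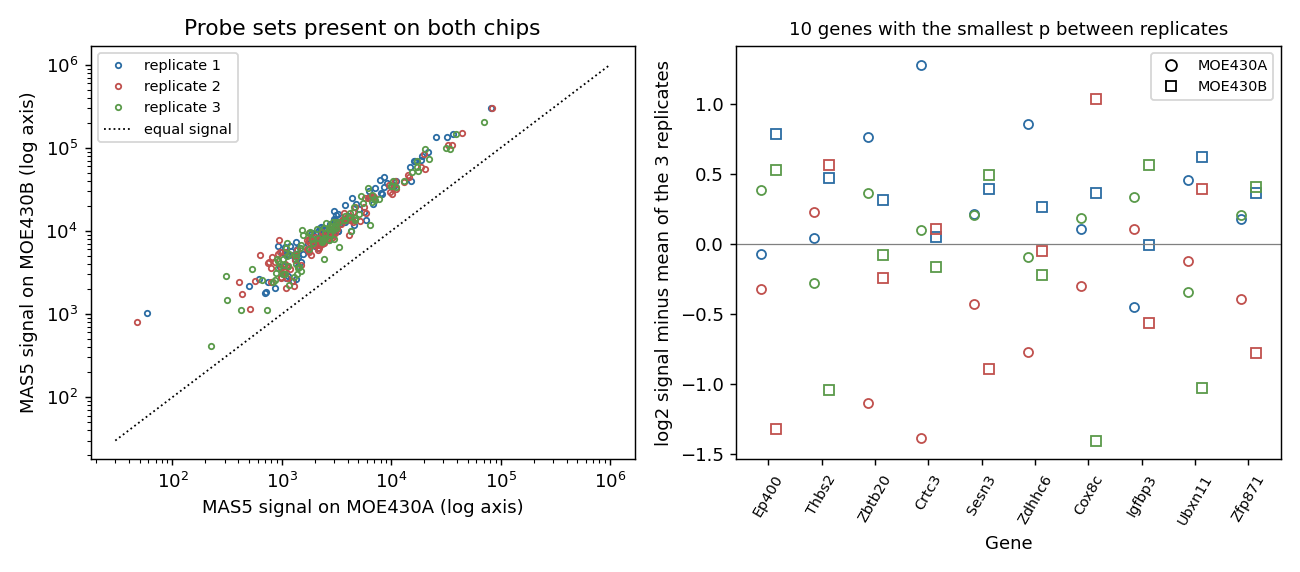
Left, MAS5 signal of the 100 shared probe sets on both chips (log axes), by replicate, with equal signal dotted; every mean lies above that line. Right, log2 signal minus the mean of 3 replicates for the 10 genes with the smallest p, with circles for MOE430A and squares for MOE430B; Cox8c runs in opposite directions on the chips.

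Of 42 medians of list deviations over 14 lists and 3 replicates, 3 lay outside the central 95% of random lists, where 2.1 are expected by chance. Differentiated muscle genes (6 genes) were at -0.21 on the log2 scale in replicate 1 and 0.22 in replicate 2, at percentiles 1.63 and 98.6. Haematopoietic and macrophage genes (7 genes) were at 0.19 in replicate 3, at percentile 98.3. These describe the arrays and are not tests.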

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

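The tests on genes above the limit on MOE430B alone and on whether the chips differ by array noise were chosen after those patterns had been seen; the test of replicate numbers was chosen before the counts were seen. The design has 1 group, so no biological explanation was tested for any pattern.

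Probe sets with no single gene name (controls left out), which no comparison above uses, also gave signal above the limit on all 3 arrays. On MOE430A these were 692 of 2246 (30.8%), against 2.68% of the reference probe sets and 35.2% of all probe sets of that chip. On MOE430B they were 286 of 7850 (3.64%), against 4.55% of the reference probe sets and 10.3% of all. The reference share there is 2 of 44 probe sets, the same ones that set the limit. It therefore cannot show whether the 286 are background or signal.

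Of 3803 genes with probe sets on both chips, 343 were above the limit by MOE430B probe sets of their own and not on MOE430A, and 380 were above on both by such probe sets. Probe sets present on both chips alone put 69 more above on both and 1 above on MOE430B only. The opposite was more frequent, with 1237 genes above on MOE430A and by no probe set on MOE430B. Genes resting only on probe sets with IDs ending in _x_at or _s_at, which can read other transcripts, were not more frequent among the first: 22.7% against 33.4% (odds ratio 0.586, 95% interval 0.415 to 0.826, Fisher's exact test, two-sided, p = 0.00167). At 22.7%, most of the 343 did not rest on such probe sets alone. The genes above on both can read other transcripts in the same way, so the odds ratio cannot exclude this source for the rest. Epcam is 1 gene of the first kind with such a probe set. Of the 343, 58.0% (Wilson interval 52.7 to 63.1) reached at least 0.5 of the limit on MOE430A, so closeness to the limit may account for part of them. Among 1773 genes above the limit on neither chip the figure was 47.3%, so that explanation separates the genes poorly. Position of the probes along the transcript stays open.

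The 7 genes called between replicates stood against 0 in each of 5 wrong matchings of the replicate numbers between chips, so 1 of 6 matchings reached the real count, and 6 matchings are too few for a share under 0.05. Array median centring left the differences about as large, with a median of 1.06 on the log2 scale before and 1.07 after, but their median SE rose from 0.267 to 0.343 and limma's prior degrees of freedom went from infinite to 6.34. After centring 0 genes passed. Whether the SE, the fewer degrees of freedom or changes in single differences ended the calls was not tested. Whether these replicates differ in any gene stays open.

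All 100 shared probe sets were called different between the chips. The medians of these probe sets per array differed by 1.92 on the log2 scale between chips (95% interval 1.62 to 2.21, n = 3), and by at most 0.33 between arrays of the same chip, which argues against array noise as the source of the chip difference. The 10 splits of the 6 arrays are too few for a share under 0.05, so counting splits decides nothing. Every array was scaled to a trimmed mean of 1500 to 1501, which removes an intensity factor common to all its probe sets. This argues against a day effect of that kind as the source. The 3' control sets moved the same way (SD, n = 3). Gapdh read 319511 ± 16820 on MOE430B against 87249 ± 5547 on MOE430A, and actin 224646 ± 374 against 58522 ± 1853. Once arrays were centred on the shared probe sets, 0 were called, so the calls rest on a shift common to them. Such a shift goes with the separate scaling of chips with unlike probe sets. The chip itself and day effects of other kinds were not told apart from that scaling.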

How the results depend on the processing

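MOE430A alone, first list only (endothelial, immediate early and tendon lists) and 2 variance models were chosen after the data were seen. Genes above the limit ranged from 4630 to 9758 against 6567, and lists passing numbered 7. The matrix list passed throughout and 9 lists passed nowhere. Cause was not tested for the changes that follow, given as adjusted p. At the 90th percentile FGF, EGF and LIF lost its call (0.179), as did hypoxia (0.0752). At the 99th, mesenchymal markers gained one (0.0289) while neural (0.104), cell cycle (0.209) and FGF (0.122) lost theirs. With 2 of 3 arrays FGF lost it (0.169). Without shared-sequence probe sets 2 lists passed, and sort antigen (0.0507), neural (0.0921), cell cycle (0.497), FGF (0.091) and hypoxia (0.0507) were lost. With 1 probe set per gene 2 passed, and sort antigen (0.0587), neural (0.29), cell cycle (0.0879), FGF (0.36) and hypoxia (0.0879) were lost. With receptors alone, read on MOE430A and moved to MOE430B, pluripotency gained (0.0248) and cell cycle lost (0.0588). With the array median 3 passed, and sort antigen (0.0749), cell cycle (0.058), FGF (0.468) and hypoxia (0.145) were lost. With MOE430A alone 3 passed, and cell cycle (0.0977), FGF (0.331), immediate early (0.0875) and hypoxia (0.0754) were lost. Expected counts rose with that background, for immediate early from 4.47 to 5.64. Leaving out a replicate gave FGF 0.0722 to 0.0858. Of 66 lead genes 47 kept their call throughout; Pdgfrb, Acta2, Fabp4, Top2a, Fgfr1 and Xist lost it without shared-sequence probe sets.

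Genes differing between replicates (limma, 7) fell to 0 with array median centring, 0 with quantile normalization, 0 of 3803 without a filter (95 unadjusted), 2 with the highest probe set, 0 with an ordinary F-test and 0 without an intensity trend (56 unadjusted). Leaving out a replicate gave 0 to 7, with 0 without replicate 2 and 3 without replicate 3; the 99th percentile gave 10 of 338. Shared probe sets called between chips fell from 100 to 0 when centred, with or without the replicate block (10 and 9 unadjusted). Centring removes only the shift common to the shared probe sets. Differences of single ones still ran from -0.95 to 0.67 on the log2 scale, so 0 calls were not fixed in advance. The replicate block without centring gave 100. The replicate numbers are a pairing by title only: deviations correlated between chips at 0.038, 0.058 and 0.12 across 618 genes, each array best with its own number, mean 0.072 (exact permutation, one-sided p = 0.167, the smallest 6 matchings allow). Without a filter the mean was 0.0033. List shifts outside the central range rose from 3 to 5 with quantile normalization. Signal over background limits all calls near the limit, more so on MOE430B, where 10.3% of probe sets passed against 35.2%.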

Other observations

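The 9 lists here were written after part of the data had been seen, the high signal of Cxcl1 included, so their tests were chosen after the result and are adjusted over these 9 alone.

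Genes of cholesterol synthesis and uptake were above the limit for 11 of 11 measured against 4.90 expected (exact test, adjusted p = 0.00111). Hmgcs1, an early enzyme of the pathway, gave 47918 ± 5376 and Cyp51 8612 ± 1249 (SD, n = 3). With 1 probe set per gene the adjusted p was 0.117. Matrix proteases and their inhibitors were above for 13 of 15 against 6.03 expected (exact test, adjusted p = 0.00141), and passed under all 11 alternatives. The stromelysin Mmp3 gave 138200 ± 23077, the cathepsin Ctsl 126650 ± 13427 and the membrane protease Mmp14 24985 ± 2168. Chemokines and cytokines were above for 12 of 18 against 5.70 expected (exact test, adjusted p = 0.00842). The monocyte attractant Ccl2 gave 28864 ± 2723, Cxcl5 17729 ± 5284 and Il6 4882 ± 1529, and Cxcl1 390610.0 ± 32604 on MOE430B, while Tnf gave 288 ± 288 and Cxcl10 185 ± 84.8. With MOE430A alone the adjusted p was 0.0677.

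The other lists did not pass in the main setting. Genes of MHC class I were above for 7 of 8 against 3.50 expected (exact test, adjusted p = 0.0501), with B2m at 40957 ± 6810; H2-K1 and H2-D1 have near copies and are uncertain. The insulin-like growth factor axis with BMP and Wnt antagonists had 11 of 17 against 6.85 (adjusted exact p = 0.106), with Igfbp5 at 60878 ± 3167 and Gas1 at 20885 ± 508, and complement 6 of 9 against 3.12 (0.116). Each of these passed under some alternatives: MHC class I at the 99th percentile limit (adjusted p = 0.0457), with 1 probe set per gene (0.00411) and with receptor families alone as reference (0.0354), the growth factor axis under the first and second of these (0.0123 and 0.0229), and complement likewise (0.0294 and 0.0413). Over all 11 alternatives adjusted p ran from 0.00411 to 0.435 for MHC class I, 0.0123 to 0.644 for the growth factor axis and 0.0294 to 0.677 for complement. MHC class II had 2 of 6 against 2.65 (adjusted exact p = 0.998), tendon 2 of 8 against 2.56 (0.998) and epithelial genes 2 of 10 against 3.74 (0.503). Dcn and Comp of the tendon list are also in fixed lists, and without them 1 of 6 was above against 1.91 expected (adjusted exact p = 0.833). Epcam, an epithelial adhesion gene, was above the limit by an MOE430B probe set of shared sequence, at 24998 ± 20402, and not on MOE430A, at 69.8 ± 21.8.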
